A study of Mus musculus with 12 samples.

How the data were processed

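Gene expression was measured by RNA sequencing in 12 libraries from 4 mouse melanoma cell lines, 3 libraries per line: MeVa2.1, MeVa2.1.dOVA, MeVa2.2 and MeVa2.2.dOVA. Group and replicate number were taken from the sample titles. Per the labels, RNA was isolated with a column kit and libraries were made with a stranded poly(A) protocol, and no treatment was given. The labels do not spell out dOVA, and the lines carrying it are treated here as derivatives of the lines whose names they extend. They also do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

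The deposited files hold whole-number read counts per gene, not normalized. Per the submitters' processing notes, STAR 2.6.0c, HTSeq 0.10.0, DESeq2 1.30.1 and the GRCm38 build were used. Each file lists 55471 gene identifiers, of which 55144 had a symbol in the name table used here. The 327 without a symbol held 0.00888% of all gene counts. Positions were taken from GENCODE M21 on GRCm38, which held 55230 of the identifiers. The 5 tally lines at the end of each file were left out of library sizes and tests. Reads in these tallies made up 35.8% to 40.0% of each library, of which reads of low mapping quality were 29.9% to 33.0%, reads outside any gene 5.11% to 8.41% and reads shared by overlapping genes 0.68% to 0.81%. Reads that map equally well to near-identical copies are not in the gene counts. Values of the H2 class I genes, the Oas, Gbp, Ifit and Slfn families, and the overlapping protocadherin gamma genes are uncertain for that reason.

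Gene counts per library ranged from 16181816 to 35627069, and the 10 most abundant genes held 3.8% to 6.44% of them. No pair of replicates agreed within counting noise: the lowest chi-square per degree of freedom between replicates was 28.55. Correlations of log2 CPM were 0.932 to 0.985 within lines and 0.856 to 0.979 between lines.

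Counts as deposited were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes with low counts were removed with filterByExpr, which left 13985 genes, and libraries were scaled by TMM. A quasi-likelihood model with one mean per line was fitted to all 12 libraries (glmQLFit), which gave 8 residual degrees of freedom, a common dispersion of 0.121 and 3.54 prior degrees of freedom. Tests used glmQLFTest with Benjamini-Hochberg adjustment over all tested genes, at an adjusted p of 0.05. Genes also changed at least 2-fold were counted separately. The 5 comparisons were each dOVA line against its parent, the parents against each other, the dOVA lines against each other, and the difference between the 2 dOVA differences. Fold changes are given on the log2 scale with the standard error (SE) implied by the F statistic of the quasi-likelihood test. Such an SE restates the test and is not a separate estimate. Levels are counts scaled by effective library size (CPM), mean ± SD over the 3 libraries of a line.

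Before the data were examined, 26 gene lists, the named-gene rule, the tests and most alternatives were fixed. Lists were tested with limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists within a comparison. They were tested again with a correlation estimated from the residuals and with fry, which asks only whether a list's genes move on balance in one direction. List members were also adjusted over the list alone. Named genes were, per direction, the 10 largest fold changes among genes past the threshold with a mean log2 CPM of at least 3, no overlap between the 2 lines' libraries and a symbol that is not a clone or predicted name. For the difference of differences, 5 per direction were taken without the overlap condition. Up to 4 members of each list, and any member of the MHC class I, interferon-stimulated, checkpoint, melanocyte differentiation and sex chromosome lists, could be named too. Chance separates 3 libraries from 3 without overlap for 10% of genes.

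A gene with no counts in one line was set against a floor of 3 counts over that line's 3 libraries. With 1 to 3 counts, the ratio is given with its exact 95% counting interval. Intervals and floors cover counting error only.

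The replicate numbers were checked for pairing by the correlation, across genes, of same-numbered libraries' deviations from their line means. For MeVa2.1.dOVA with MeVa2.1 these were 0.503, 0.488 and 0.534, for MeVa2.1 with MeVa2.2 they were 0.429, 0.405 and 0.328, and for MeVa2.1.dOVA with MeVa2.2.dOVA they were 0.105, 0.516 and 0.416. All exceeded 0.1, the limit used for treating numbers as pairs, though 0.105 did so only by little. The pairing comes from these values, since no label says what a number stands for. For those comparisons the counts of changed genes and the list calls with the replicate number as a block are given beside those without. The block was fitted jointly over all 12 libraries, so these values also rest on the MeVa2.2 lines. For MeVa2.2.dOVA with MeVa2.2 the correlations were 0.082, 0.64 and 0.521, and the numbers were not treated as pairs because 0.082 lay under the limit. The limit thus parts 0.082 from 0.105, which are close, and the block count for this comparison is given in the closing section. Because the pairing was read from the same data, values with the block are not independent support for it.

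The fit was tested on simulated counts with each gene's mean over all libraries and the real library sizes and dispersions. In them 200 genes changed in 1 line. Genes and libraries were drawn independently, without the correlation between same-numbered libraries found in the real data. The recovery and false calls therefore do not cover errors that come from such shared structure. With MeVa2.1.dOVA changed and 13763 genes tested, the comparison with MeVa2.1 recovered 9.2% of 2-fold, 62.7% of 4-fold and 81.2% of 8-fold changes, with 6 false calls. The comparison with MeVa2.2.dOVA recovered 13.8%, 61.2% and 79.7%, and the difference of differences 1.5%, 35.8% and 57.8%. With MeVa2.2 changed and 13751 genes tested, the comparison of MeVa2.2.dOVA with MeVa2.2 recovered 9.1%, 68.7% and 78.1% and the comparison of the parents 9.1%, 59.7% and 78.1%. Alternatives were DESeq2 size factors, upper-quartile factors, no filter, a filter of 1 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, the replicate block, a fit to the compared lines alone and each library left out in turn. Leaving out all libraries of one number was added after seeing the data.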

Results

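The data are RNA-seq gene counts from 4 mouse melanoma cell lines grown untreated, MeVa2.1, MeVa2.1.dOVA, MeVa2.2 and MeVa2.2.dOVA, with 3 libraries each. The series title calls MeVa2.1.dOVA immune-refractory, and the labels give skin and subcutaneous tumour as the source. Total gene counts were 18521748, 19204452 and 35627069 for replicates 1, 2 and 3 of MeVa2.1. They were 16181816, 17412714 and 34744387 for MeVa2.1.dOVA, 16896708, 18988498 and 26291546 for MeVa2.2, and 18543632, 18753182 and 33683165 for MeVa2.2.dOVA. In the plot of principal components, component 1 held 46.9% of the variance and component 2 held 19.8%. Replicate 2 of MeVa2.1.dOVA lay apart from its line on component 2, at -87.75 against -13.75 and -25.17 for replicates 1 and 3. Replicate 2 of MeVa2.2 also lay apart from its line, at 60.68 on component 1 against 8.99 and -6.87 and at -13.60 on component 2 against 53.75 and 72.09. It correlated at 0.969 and 0.964 with replicates 1 and 2 of MeVa2.2.dOVA and at 0.956 and 0.932 with replicates 1 and 3 of its own line.

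Axl and Ptprc are given here as markers chosen after their values were seen. All lines had high Axl, a receptor tyrosine kinase of dedifferentiated melanoma, at 1532 ± 167 CPM in MeVa2.1, 1736 ± 136 in MeVa2.1.dOVA, 1495 ± 215 in MeVa2.2 and 1299 ± 78.4 in MeVa2.2.dOVA (SD, n = 3). Tyr, the tyrosinase of melanin synthesis, was at 0.63 ± 0.483, 0.58 ± 0.131, 0.86 ± 1.32 and 0.0806 ± 0.0792 CPM in the same order. Dct, another melanin enzyme, was at 15.56 CPM in replicate 1 of MeVa2.2, 0 in replicate 2 and 2.28 in replicate 3. Ptprc, the leukocyte marker CD45, did not exceed 0.23 CPM in any library. Summed over the 19 listed immune cell markers, the level was highest in replicate 1 of each line. There it was 17.8 CPM in MeVa2.1, 14.7 in MeVa2.1.dOVA, 10.2 in MeVa2.2 and 9.97 in MeVa2.2.dOVA, against 3.66 to 8.44 in the other libraries.

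**Figure D1:**
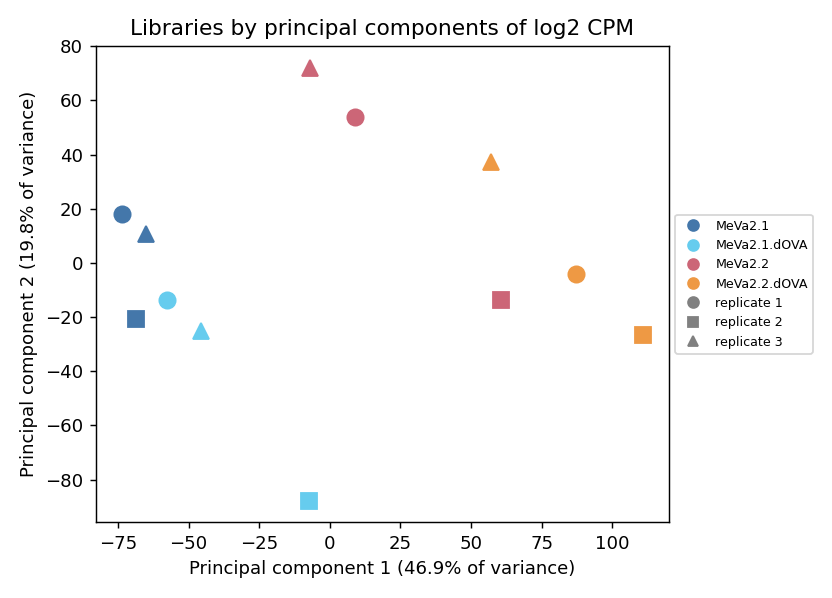
Principal components 1 and 2 of log2 CPM over tested genes, 1 point per library, coloured by line and shaped by replicate number. Component 1 (46.9% of variance) runs from the MeVa2.1 libraries to those of MeVa2.2.dOVA, and replicate 2 of MeVa2.1.dOVA is lowest on component 2 (19.8%), at -87.75.

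The comparison of MeVa2.1.dOVA with MeVa2.1 asked how the dOVA line differs from its parent. Among the genes that fell, Hpse, the heparan sulfate-cleaving enzyme heparanase, was at 1.98 ± 0.934 CPM against 26.7 ± 4.62 (log2 fold change -3.76, SE 0.55, adjusted p = 0.0193), and Sulf1, a heparan sulfate sulfatase, fell by 5.72 (SE 1.09). The lysosomal cathepsins Ctsk (-3.20, SE 0.46) and Ctsc (-3.18, SE 0.49) and the protease inhibitor Serpine2 (-3.52, SE 0.62) were lower too. Cd93, a surface glycoprotein (chromosome 2, 148436640 to 148443563 on GRCm38; -5.80, SE 1.07), Dchs1, a large protocadherin (-4.32, SE 0.74), Bcl6b, a transcriptional repressor (-3.87, SE 0.57), Thsd7a (-3.42, SE 0.58) and the long non-coding RNA Carmn (-3.27, SE 0.40) complete the named genes that fell. Among the genes that rose were Il1rl1, the receptor for interleukin-33, at 696 ± 359 CPM against 142 ± 35.0 (2.29, SE 0.43, adjusted p = 0.0493), and the LIM-domain gene Fhl1 (2.01, SE 0.32). Glipr1 (2.31, SE 0.42), the neural transcription factor Npas3 (1.59, SE 0.24) and Gpatch4 (1.05, SE 0.19) rose as well.

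Fibroblast markers, such as decorin and Thy1, were lower as a list in MeVa2.1.dOVA than in MeVa2.1, with a median log2 fold change of -2.34 over 10 tested genes (camera adjusted p = 5.16e-05). Dcn, which encodes the matrix proteoglycan decorin, was the 1 member that fell (-2.32, SE 0.39), and 3 fell adjusted over the list alone, the others being Thy1 and Fap. Extracellular matrix and mesenchymal genes (median -0.66, 28 tested, adjusted p = 1.18e-04) and adhesion genes (median -0.54, 21 tested, adjusted p = 1.98e-04) were lower as lists with no member called, and adjusted over the list alone 0 and 3 fell, the 3 being Itga2, Itga6 and Alcam. Chemokines and cytokines were lower as a list (median -0.60, 25 tested, adjusted p = 0.00671), with Cx3cl1, a membrane-bound chemokine, the 1 called member (-2.55, SE 0.46) and 3 adjusted over the list alone. Schwann and neural markers (median -1.05, 8 tested, adjusted p = 0.0382), mitochondrially encoded mRNAs, kept as a sign of RNA quality (median -0.37, 7 tested, adjusted p = 0.0105), and MHC class I genes (median -0.37, 19 tested, adjusted p = 0.0448) were lower with 0 members called, also adjusted over the list alone. None of these 7 list calls held with an estimated correlation (adjusted p = 0.598 for each). Members called over all genes with the replicate number as a block were 3 fibroblast markers, 4 matrix genes, 6 adhesion genes and 1 MHC class I gene, all lower. Of the chemokines and cytokines 1 was higher and 3 lower, and 0 were called in the Schwann and mitochondrial lists. In that fit the list tests gave an adjusted p of 1.05e-04 for the fibroblast and adhesion lists, 8.54e-05 for matrix genes and 0.0143 for chemokines. It was 0.00388 for mitochondrial mRNAs, 0.0280 for MHC class I and 0.0507 for the Schwann list, whose call was lost. The Schwann call was also lost without MeVa2.1 replicate 1 (0.175) and without MeVa2.1.dOVA replicate 3 (0.0899). The MHC call was lost without MeVa2.1 replicate 1 (0.161), MeVa2.1.dOVA replicate 3 (0.282), MeVa2.2.dOVA replicate 1 (0.0520) or replicate 2 (0.0542), the chemokine call without MeVa2.1 replicate 1 (0.121) and the mitochondrial call without MeVa2.1.dOVA replicate 3 (0.117).

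Of 13985 genes tested, 68 differed between MeVa2.1.dOVA and MeVa2.1, 14 higher and 54 lower, all 68 by at least 2-fold (edgeR quasi-likelihood test). With the replicate number as a block the count was 364, of which 75 were higher and 289 lower, and all 68 were among them. The count was 1 without MeVa2.1 replicate 1, MeVa2.1 replicate 2, MeVa2.1.dOVA replicate 2 or MeVa2.1.dOVA replicate 3, and 9 without MeVa2.1.dOVA replicate 1. A fit to these 2 lines alone called 25, of which 21 were among the 68, the DESeq2 Wald test 389 and a fit with no filter 272. The count was 40 without MeVa2.2 replicate 1, 32 without MeVa2.2.dOVA replicate 1 and 43 without MeVa2.2.dOVA replicate 2, libraries that enter this comparison through the shared spread.

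In the comparison of MeVa2.2.dOVA with MeVa2.2, interferon-stimulated genes were higher. All 30 tested members of the list had a positive fold change, with a median of 2.13. Ddx58, the cytosolic RNA sensor RIG-I (chromosome 4, 40203773 to 40239828), was at 242 ± 95.1 CPM against 55.0 ± 32.6 (log2 fold change 2.14, SE 0.49, adjusted p = 0.0495). Gbp3, a guanylate-binding protein (3.35, SE 0.76), and the oligoadenylate synthetases Oas1a (6.54, SE 1.23) and Oas2 (5.85, SE 1.20) also rose. These 4 were called over all genes, and 23 rose adjusted over the list alone. The list test gave an adjusted p of 2.48e-19, and adjusted p = 0.332 with an estimated correlation. The MeVa2.2 libraries differed among themselves, with mean log2 CPM over this list of 4.26, 2.68 and 1.57 for replicates 1, 2 and 3, against 5.08, 4.67 and 6.39 in MeVa2.2.dOVA.

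MHC class I antigen presentation genes were higher as a list in MeVa2.2.dOVA than in MeVa2.2 (median 1.17, 19 tested, adjusted p = 1.25e-06, and adjusted p = 0.332 with an estimated correlation). The class I heavy chains H2-K1, at 79.3 ± 11.5 CPM against 20.9 ± 8.84 (1.92, SE 0.43), and H2-D1, at 197 ± 7.40 against 88.0 ± 26.2 (1.17, SE 0.26), rose, with the reservation that reads shared with other H2 genes are not counted. Adjusted over the list alone, 12 members rose and 1, the chaperone Pdia3, fell. Other genes that rose were Trim30a (3.14, SE 0.64), Herc6 (2.57, SE 0.56), Dtx3l (2.36, SE 0.54) and Rnf213 (2.39, SE 0.43), all of which encode ring-finger or HECT-type ubiquitin ligases, and Lgals3bp, a secreted galectin-binding glycoprotein (2.63, SE 0.58). Each of them was highest in MeVa2.2.dOVA replicate 3, where the mean log2 CPM over the interferon-stimulated list was highest too (6.39). They may therefore not be a finding separate from that list. The transcription factor gene Shox2 (2.44, SE 0.37), Setbp1 (2.39, SE 0.44) and the glutamate receptor gene Grik5 (2.27, SE 0.27) rose as well.

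Extracellular matrix and mesenchymal genes were lower as a list in MeVa2.2.dOVA than in MeVa2.2 (median -0.85, 28 tested, adjusted p = 6.39e-06), with the basement membrane collagen Col4a2 called (-1.40, SE 0.27) and 9 fallen adjusted over the list alone. Fibroblast markers were lower (median -2.26, 10 tested, adjusted p = 2.90e-04), with Pdgfra, a growth factor receptor, at 30.6 ± 21.1 CPM against 187 ± 17.6 (-2.61, SE 0.59), Thy1 (-6.49, SE 1.09) and Dcn (-2.49, SE 0.42) called, and 5 adjusted over the list alone. Of the adhesion genes (median -0.93, 21 tested, adjusted p = 3.43e-04), the integrins Itga6 (-1.51, SE 0.26) and Itgb3 (-4.89, SE 1.01) and the junction gene Jam2 (-2.82, SE 0.64) fell, 4 adjusted over the list alone. With an estimated correlation, adjusted p = 0.332 for each of these 3 lists. Libraries of the lines overlapped in the mean log2 CPM over the matrix list, with 8.42, 7.53 and 8.55 for replicates 1, 2 and 3 of MeVa2.2 against 6.70, 6.77 and 7.75 in MeVa2.2.dOVA, and over the adhesion list, with 5.42, 4.27 and 5.46 against 4.24, 3.78 and 4.31. Col15a1 (-7.40, SE 1.62), Sparcl1, a matrix glycoprotein (-6.88, SE 0.82), Gldn, gliomedin of glial contacts (-6.52, SE 0.69), Tspan11 (-5.89, SE 0.96), Slco3a1 (-5.50, SE 0.83), Krt20 (-5.26, SE 1.16), Serping1, the complement C1 inhibitor (-4.99, SE 1.06), Efr3b (-4.97, SE 1.10) and Slc14a1 (-4.77, SE 1.04) were the other named genes that fell. The MeVa2.2 libraries were not uniform in them: in each of these genes and in Itgb3, replicate 2 was the lowest of the line. Tspan11 was at 6.04, 0.864 and 12.5 CPM in replicates 1, 2 and 3 of MeVa2.2, and Col15a1 at 9.70, 1.57 and 19.6.

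Further lists differed between MeVa2.2.dOVA and MeVa2.2. Wnt/beta-catenin targets were lower (median -0.99, 11 tested, adjusted p = 0.0175), with Dkk2, a secreted Wnt regulator, at 23.7 ± 19.9 CPM against 388 ± 233 (-4.03, SE 0.90), and Sfrp1, a secreted Wnt antagonist, at least 53.3-fold lower, the 2 called members. Adjusted over the list alone 5 fell. MAPK output genes were lower (median -0.38, 19 tested, adjusted p = 0.0175), with Etv5 called (-1.03, SE 0.20) and 4 fallen and 1 risen adjusted over the list alone. Neural crest-like genes (median -0.39, 27 tested, adjusted p = 0.0122) had Egfr called (-3.88, SE 0.85) and 5 adjusted over the list alone, and hypoxia and glycolysis genes (median -0.37, 22 tested, adjusted p = 0.0348) had Adm (-3.70, SE 0.72) and the lactate transporter Slc16a3 (-5.06, SE 1.15) called, also 2 adjusted over the list alone. Cholesterol synthesis and uptake genes were lower (median -0.56, 19 of 19 negative, adjusted p = 0.0427), while integrated stress response genes (median 0.30, 18 tested, adjusted p = 0.0107) and melanoma drivers and tumour suppressors (median 0.40, 16 tested, adjusted p = 0.0256) were higher, with 0 members called in these 3 lists, also adjusted over the list alone. With an estimated correlation, adjusted p = 0.332 for the Wnt and neural crest-like lists, 0.431 for MAPK, 0.760 for cholesterol and 0.477 for the other 3. The test of the cholesterol list turned its direction without MeVa2.2 replicate 3 (adjusted p = 0.473) and lost its call without MeVa2.2.dOVA replicate 1 (0.168) or 2 (0.189). The stress list was lost without MeVa2.2 replicate 3 (0.289), the Wnt list without MeVa2.2 replicate 3 (0.0537) or MeVa2.2.dOVA replicate 3 (0.0588), and the MAPK list without MeVa2.2 replicate 2 (0.0714) or MeVa2.2.dOVA replicate 3 (0.401). The hypoxia list was lost without MeVa2.2 replicate 3 (0.180), MeVa2.2.dOVA replicate 1 (0.0503) or 2 (0.0799). The driver list was lost without any of 10 libraries, at 0.0735, 0.0617 and 0.0551 without MeVa2.1 replicates 1, 2 and 3, 0.0526, 0.0534 and 0.0543 without those of MeVa2.1.dOVA, 0.0639 and 0.104 without MeVa2.2 replicates 1 and 3, and 0.111 and 0.265 without MeVa2.2.dOVA replicates 1 and 2.

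Between MeVa2.2.dOVA and MeVa2.2, 278 genes differed, 59 higher and 219 lower, of which 250 differed by at least 2-fold (edgeR quasi-likelihood test). Ednrb, the endothelin receptor of melanocyte precursors, was the 1 melanocyte differentiation gene among them, with 1 count in MeVa2.2.dOVA against 202, a ratio of 238 (95% counting interval 42.1 to 9426). The count of changed genes was 145 and 154 without MeVa2.1 replicates 1 and 2, 158 and 156 without MeVa2.1.dOVA replicates 1 and 3, and 63, 447 and 94 without MeVa2.2 replicates 1, 2 and 3. It was 80 and 20 without MeVa2.2.dOVA replicates 1 and 2. A fit to these 2 lines alone called 5, of which 3 were among the 278, while the DESeq2 Wald test called 950 and a fit with no filter 729.

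**Figure D2:**
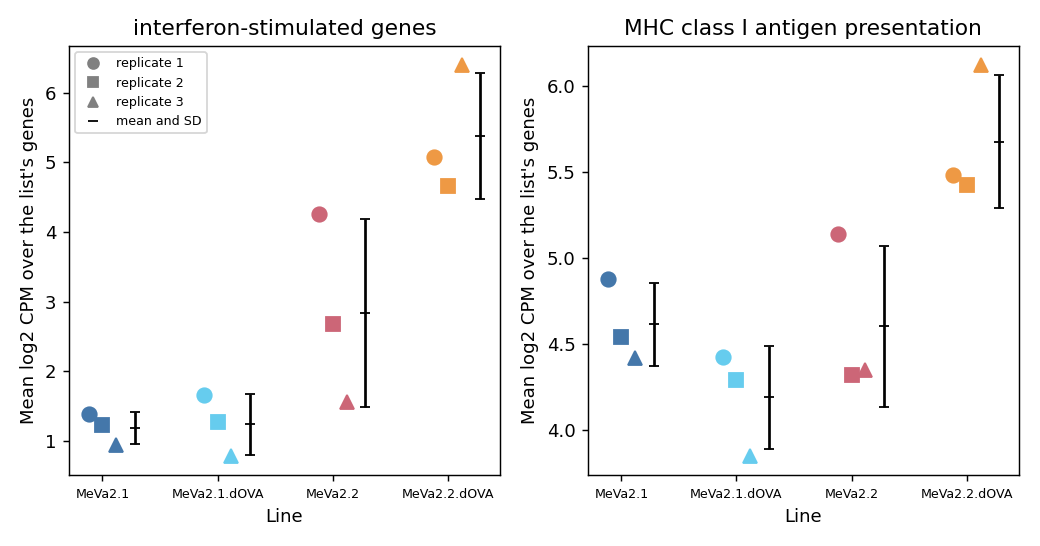
Mean log2 CPM over the interferon-stimulated genes (left) and the MHC class I antigen presentation genes (right), 1 point per library, with the mean and SD of each line's 3 libraries beside the points. The interferon-stimulated mean lies between 4.67 and 6.39 in MeVa2.2.dOVA and between 0.787 and 1.66 in MeVa2.1.dOVA, and the MeVa2.2 libraries spread from 1.57 to 4.26.

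The difference of the dOVA differences asked whether dOVA lines depart from their parents by different amounts in the 2 origins. Sirpa, the receptor that binds CD47 (chromosome 2, 129592835 to 129632228), was at 88.8 ± 6.08 CPM in MeVa2.1.dOVA against 96.9 ± 21.01 in MeVa2.1, and at 0.983 ± 0.448 in MeVa2.2.dOVA against 12.2 ± 0.393 in MeVa2.2 (difference 3.55, SE 0.40, adjusted p = 0.0119). Rnf130 (3.49, SE 0.53), Rap1gap2, a regulator of the small GTPase Rap (3.11, SE 0.43), and the pseudokinase gene Trib1 (2.16, SE 0.32) differed in the same direction. Carmn was at 3.34 ± 1.21 CPM in MeVa2.1.dOVA against 32.1 ± 10.7 in MeVa2.1, and at 1.60 ± 0.498 against 1.18 ± 0.434 in the MeVa2.2 pair (-3.72, SE 0.56). Pcdhgb2, a protocadherin that overlaps its cluster neighbours and is therefore uncertain, also differed (-2.49, SE 0.35).

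Interferon-stimulated genes had a median difference of differences of -1.99 (30 tested, adjusted p = 2.85e-16, and adjusted p = 0.563 with an estimated correlation), with 0 members called, also adjusted over the list alone. MHC class I genes had a median of -1.31 (19 tested, adjusted p = 1.27e-09, and adjusted p = 0.243 with an estimated correlation), with 0 members called and 9 lower adjusted over the list alone, among them H2-K1 (-3.20, SE 0.60) and Tap2 of the peptide transporter (-3.10, SE 0.77). Chemokines and cytokines had a median of -0.70 (25 tested, adjusted p = 0.00233, and adjusted p = 0.563 with an estimated correlation), with 0 called and, adjusted over the list alone, 2 higher and 3 lower. Over all genes 12 were called, 7 higher and 5 lower, and 1187 had an unadjusted p under 0.05. The DESeq2 Wald test called 272 and a fit with no filter 161, all 12 among each. The edgeR count was 0 without MeVa2.1.dOVA replicate 3 (1125 at an unadjusted p under 0.05, 201 called by DESeq2) or MeVa2.2 replicate 1 (992 and 244), 1 without MeVa2.1 replicate 1 or 3, and 4 without MeVa2.1 replicate 2, MeVa2.1.dOVA replicate 1 or 2, or MeVa2.2.dOVA replicate 2 or 3.

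The dOVA comparisons shared 17 genes called in the same direction, 1 higher and 16 lower in both, where independent lists would share 0.06 and 0.85, and 1 gene was called in opposite directions. Cx3cl1 (-2.55, SE 0.46, and -2.53, SE 0.45) and Dcn (-2.32, SE 0.39, and -2.49, SE 0.42) fell in both. Fold changes correlated across genes, which are not independent replicates, with Pearson's r of 0.438 and Spearman's rho of 0.368. When the 6 libraries of each comparison were relabelled, 22 of 200 relabellings, the real one included, gave a correlation at least as large as the 0.411 of the real labels on log2 CPM, the highest other being 0.632.

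The comparison of MeVa2.1 with MeVa2.2 asked how the parental lines differ. Neighbouring genes on chromosome 4 were nearly silent in MeVa2.1. Mtap, methylthioadenosine phosphorylase of methionine salvage (chromosome 4, 89137122 to 89181081), was at 0.274 ± 0.145 CPM against 848 ± 115 (log2 fold change -11.62, SE 0.38, adjusted p = 3.32e-08). Klhl9, a ubiquitin ligase adaptor (88718292 to 88722465), had 1 count against 7392, a ratio of 8701 (95% counting interval 1561 to 343700), and the non-coding RNA Wincr1 (89050308 to 89084614) was at least 541-fold lower. Cdkn2a, a tumour suppressor locus of cell-cycle inhibitors (89274471 to 89294653), had 0 counts against 52 and was at least 20.4-fold lower.

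Lower genes in MeVa2.1 than in MeVa2.2 included interferon-stimulated genes (median -1.97, 30 tested, adjusted p = 1.14e-07, and adjusted p = 0.924 with an estimated correlation). Blocked on the replicate number, adjusted p was 2.94e-06. Of the list 7 fell, and 16 fell adjusted over the list alone. Irf9, a subunit of the interferon-activated transcription factor, was at 9.02 ± 1.79 CPM against 42.1 ± 24.6 (-2.22, SE 0.43), and Ifi44 fell by 5.27 (SE 0.97). Usp18, the ISG15 protease, had 3 counts against 750, a ratio of 294 (95% counting interval 100.3 to 1430). Slfn8, of a family induced by interferon, had a ratio of 200.5 (68.2 to 975). The MeVa2.2 libraries were far from uniform, with Usp18 at 31.4, 9.45 and 1.33 CPM in replicates 1, 2 and 3. Mean log2 CPM over the interferon list was 4.26, 2.68 and 1.57 in these, against 1.39, 1.23 and 0.944 in MeVa2.1. The calcium channel subunit Cacna2d1 (-7.89, SE 0.56), Pear1 (-7.34, SE 0.58), Epb41l4a (-7.32, SE 0.65) and the transcription factor Osr2 (-5.85, SE 0.84) fell too.

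Genes higher in MeVa2.1 than in MeVa2.2 included Pik3cd, the delta catalytic subunit of phosphoinositide 3-kinase (chromosome 4, 149649168 to 149702571), at 164 ± 22.6 CPM against 1.18 ± 0.548 (7.12, SE 0.51, adjusted p = 1.97e-05), Scara5, a ferritin receptor (7.04, SE 0.64), and the glucose transporter Slc2a3 (6.95, SE 0.67). Tfap2b, a neural crest transcription factor (6.82, SE 0.75), Arhgap28 (6.74, SE 0.62), the small heat shock protein Hspb8 (6.21, SE 0.40), the BMP antagonist Chrdl1 (5.72, SE 0.71), the potassium channel Kcnj12 (5.59, SE 0.72), Afap1l2 (5.47, SE 0.48) and the proton pump subunit Atp6v0d2 (5.09, SE 1.17) rose too. Schwann and neural markers were higher as a list (median 1.10, 8 tested, adjusted p = 0.0275, and adjusted p = 0.924 with an estimated correlation), with 2 members called, also adjusted over the list alone. Adjusted p was 0.0239 with the replicate number as a block. Extracellular matrix and mesenchymal genes (median 0.45, 28 tested, adjusted p = 0.0653) and adhesion genes (median 0.43, 21 tested, adjusted p = 0.0857) did not pass without the block and passed with it (adjusted p = 0.0239 and 0.0444), and adjusted p = 0.924 with an estimated correlation for both. Without the block 2 members of each rose, and adjusted over the list alone 2 matrix genes rose, and 4 adhesion genes rose and 1 fell. The called members of the Schwann list were Foxd3, a neural crest transcription factor, with 518 counts against 1, a ratio of 440.1 (95% counting interval 78.6 to 17420), and Ngfr, the nerve growth factor receptor (4.09, SE 1.01). Cd276, the checkpoint ligand B7-H3, rose (3.36, SE 0.50), as did Tyk2 (1.49, SE 0.33) and Socs3 (1.74, SE 0.33) of interferon and cytokine receptor signalling. The Schwann list call was lost without MeVa2.1 replicate 1 (adjusted p = 0.188) or MeVa2.1.dOVA replicate 2 (0.0525).

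Between the parental lines 627 genes differed, 395 higher and 232 lower in MeVa2.1, of which 555 differed by at least 2-fold (edgeR quasi-likelihood test). With the replicate number as a block the count was 1330, 838 higher and 492 lower, and 626 were called in both fits. The count was 371 and 279 without MeVa2.1 replicates 1 and 2, and 314 and 365 without MeVa2.2 replicates 1 and 2. A fit to the parental lines alone called 397, of which 367 were among the 627, while the DESeq2 Wald test called 1216 and a fit with no filter 969.

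**Figure D3:**
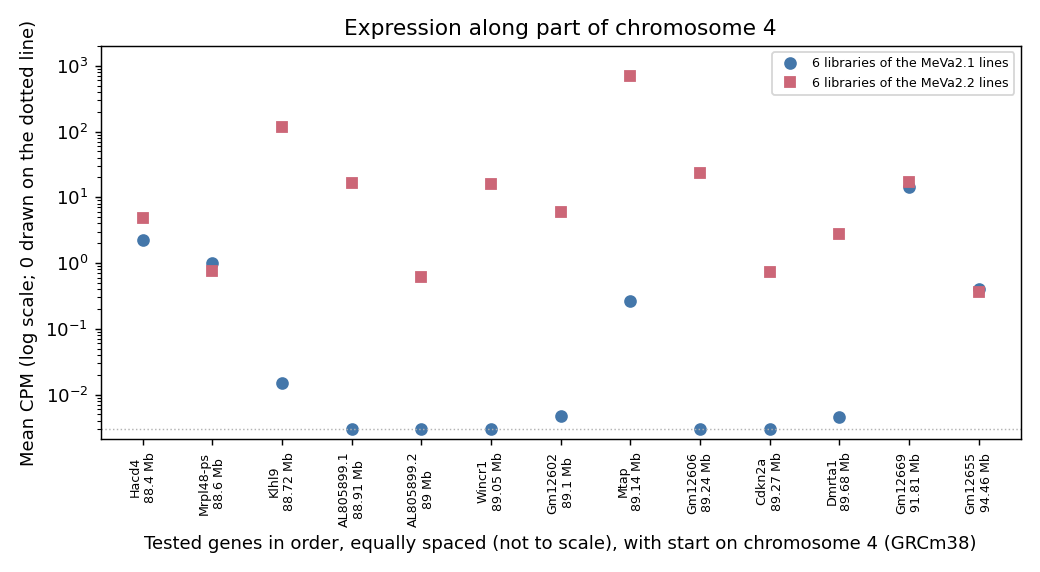
Mean CPM (log axis) of tested genes along part of chromosome 4, in chromosome order with equal spacing, as blue circles for the 6 libraries of the MeVa2.1 lines and red squares for the 6 of the MeVa2.2 lines. The genes from Klhl9 to Dmrta1 lie far lower in the MeVa2.1 lines, with Mtap at 0.264 against 701 CPM, while Mrpl48-ps and Gm12669 on either side lie at 129% and 83.8% of the MeVa2.2 level. Mrpl48-ps, a pseudogene by its symbol, is at 0.994 against 0.769 CPM, and the next gene outward, Hacd4, lies at 46.1%. Genes shown besides Klhl9, Wincr1, Mtap and Cdkn2a were chosen after their values were seen.

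MeVa2.1.dOVA was compared with MeVa2.2.dOVA because the series title sets MeVa2.1.dOVA apart as immune-refractory. Interferon-stimulated genes were lower in MeVa2.1.dOVA: 26 of 30 tested members fell, 27 adjusted over the list alone, and the median was -3.88, the same with the genes at 0 counts set to their bound. Irf9 was at 8.04 ± 1.86 CPM against 97.6 ± 19.5 (log2 fold change -3.60, SE 0.46, adjusted p = 5.82e-04). Irf7, a regulator of interferon transcription, fell by 7.17 (SE 1.03), Ifi44 by 8.17 (SE 1.08) and Isg15, a ubiquitin-like modifier, by 3.24 (SE 0.84). Oas1a and Oas2 had 0 counts in MeVa2.1.dOVA and were at least 203.6-fold and at least 465-fold lower, and Usp18 had 3 counts against 7595, a ratio of 2364 (95% counting interval 809 to 11470). The list test gave an adjusted p of 9.22e-21, 3.50e-16 with the replicate number as a block, and adjusted p = 0.483 with an estimated correlation.

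MHC class I antigen presentation genes were lower too (median -1.33, 19 tested, adjusted p = 2.33e-06, and adjusted p = 0.483 with an estimated correlation). Blocking on the replicate number gave an adjusted p of 3.63e-06. Of the members 9 fell, and 13 adjusted over the list alone. H2-K1 was at 15.9 ± 4.81 CPM against 79.3 ± 11.5 (-2.33, SE 0.44), and H2-D1 was at 77.9 ± 11.5 against 197 ± 7.40 (-1.34, SE 0.26). B2m, the invariant light chain, fell by 0.96 (SE 0.23), Tap2 by 2.54 (SE 0.56) and the peptide-trimming enzyme Erap1 by 1.33 (SE 0.23). Tyk2 (1.19, SE 0.33) and Socs3 (1.32, SE 0.32) rose and the interferon-gamma receptor subunit Ifngr2 fell (-1.03, SE 0.30), while the interferon receptor signalling list as a whole did not pass (adjusted p = 0.831). Cd276 was the 1 checkpoint gene called, and it rose, at 80.8 ± 20.8 CPM against 10.1 ± 6.27 (adjusted p = 0.00296).

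Extracellular matrix and mesenchymal genes were higher as a list in MeVa2.1.dOVA than in MeVa2.2.dOVA (median 0.97, 28 tested, adjusted p = 0.0234, and adjusted p = 0.685 with an estimated correlation). Of them 6 rose, among them Lox, a collagen cross-linking enzyme (7.30, SE 1.16), Fbln2 (5.13, SE 0.69) and Timp3, a metalloproteinase inhibitor (2.71, SE 0.56), and 2 fell. Adjusted over the list alone 11 rose and 3 fell. Cholesterol genes were higher as a list (median 0.72, 19 of 19 positive, adjusted p = 0.0234, and adjusted p = 0.747 with an estimated correlation), with Sqle, squalene epoxidase, called (1.28, SE 0.34) and 0 adjusted over the list alone. In the fit with the replicate number as a block, adjusted p was 0.0158 for the matrix and 0.009 for the cholesterol list. The matrix and cholesterol calls were lost without MeVa2.1.dOVA replicate 1 (adjusted p = 0.0733 for both), MeVa2.1.dOVA replicate 3 (0.0858 and 0.0746), MeVa2.2.dOVA replicate 1 (0.0826 and 0.0649) or MeVa2.2.dOVA replicate 2 (0.0603 and 0.0840). Lists that passed with the block and not without it were chemokines and cytokines (median -0.85, 25 tested, adjusted p = 0.0428 against 0.0879), Wnt/beta-catenin targets (median 1.49, 11 tested, 0.0471 against 0.0605) and hypoxia and glycolysis (median 0.61, 22 tested, 0.0379 against 0.0605), with adjusted p = 0.685 for each with an estimated correlation. Without the block 2 chemokine genes rose and 4 fell, 5 Wnt targets rose and 2 fell, and 5 hypoxia genes rose and 1 fell. Adjusted over the list alone these were 3 and 5, 5 and 2, and 5 and 1.

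Single genes that were higher in MeVa2.1.dOVA than in MeVa2.2.dOVA included Scara5, at 233 ± 16.1 CPM against 0.411 ± 0.108 (9.08, SE 0.72, adjusted p = 3.60e-05), Sparcl1 (8.48, SE 0.85), Hspb8 (8.48, SE 0.46), Atp6v0d2 (8.39, SE 1.40), Slco3a1 (8.18, SE 0.87), Pik3cd (7.95, SE 0.53) and Col15a1 (9.56, SE 1.64). With 2 counts each in MeVa2.2.dOVA, Tfap2b had a ratio of 3812 (95% counting interval 1055 to 31490), Slc2a3 of 913 (252 to 7543) and Arhgap28 of 845 (234 to 6982). Klhl9, with 1 count in MeVa2.1.dOVA, had a ratio of 7869 (1412 to 310900) in the other direction, Slc6a15, an amino acid transporter, of 2285 (409.8 to 90300) and Pear1 of 534 (182 to 2592). Mtap (-10.97, SE 0.38), Slfn8 (-9.04, SE 1.09) and Cacna2d1 (-7.60, SE 0.54) fell, and Wincr1 was at least 217-fold lower.

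Between the dOVA lines 1574 genes differed, 902 higher and 672 lower in MeVa2.1.dOVA, of which 1248 differed by at least 2-fold (edgeR quasi-likelihood test). With the replicate number as a block the count was 3079, 1737 higher and 1342 lower, and 1573 were called in both fits. The count was 813 and 946 without MeVa2.1.dOVA replicates 1 and 3, and 816, 796 and 2578 without MeVa2.2.dOVA replicates 1, 2 and 3. A fit to the dOVA lines alone called 1025, of which 983 were among the 1574, and the DESeq2 Wald test called 2380. The comparisons between origins, of parents and of dOVA lines, shared 417 genes in the same direction, 269 higher and 148 lower, where independent lists would share 25.48 and 11.15, and 2 were called in opposite directions. With the replicate number as a block, 856 were shared. Their fold changes correlated with Pearson's r of 0.738 and Spearman's rho of 0.591, and 2 of 200 relabellings, the real one included, reached the 0.716 of the real labels on log2 CPM.

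**Figure D4:**
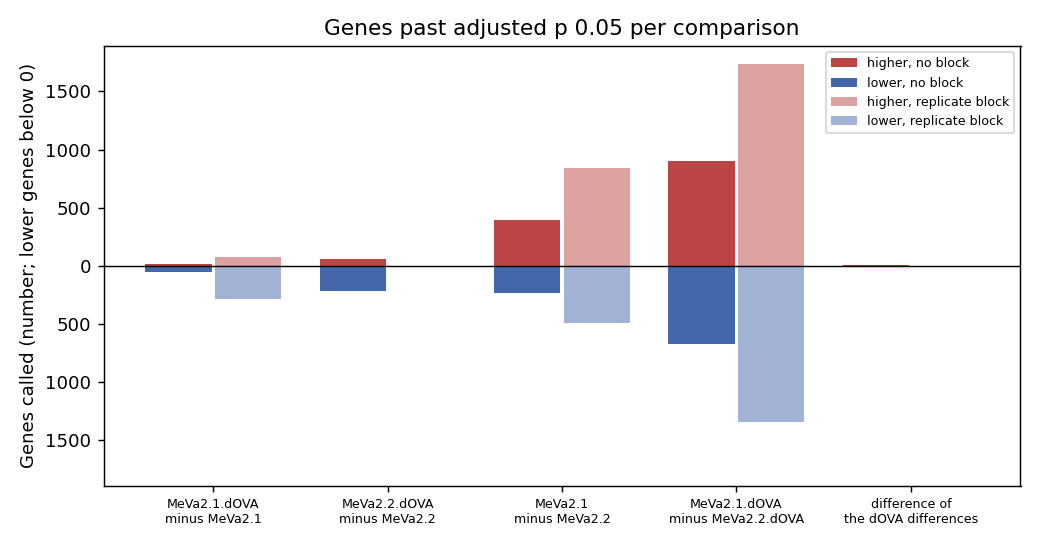
Number of genes past the threshold in each comparison, higher above 0 and lower below, without (solid) and, where the numbers were treated as pairs, with (pale) the replicate number as a block. The comparison of the dOVA lines has the tallest bars, 902 higher and 672 lower without the block, and the difference of the dOVA differences has 7 and 5.

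Other lists passed camera with the preset correlation and no block in none of the 5 comparisons. Their lowest adjusted p was 0.342 for interferon receptor signalling, 0.0938 for checkpoint and immunosuppressive genes, 0.0610 for NF-kB genes, for melanocyte differentiation and for endothelial markers, and 0.199 for death receptor and killing resistance genes. It was 0.0778 for proliferation, 0.257 for immediate early and heat shock genes, 0.699 for immune cell markers, 0.505 for keratinocyte markers and 0.758 for sex chromosome transcripts. By fry, melanocyte differentiation and endothelial markers (adjusted p = 0.0431 for both) and death receptor and killing resistance genes (0.0484) passed in MeVa2.2.dOVA against MeVa2.2. Between the dOVA lines fry passed Wnt/beta-catenin targets (0.0144) and Schwann and neural markers (0.00498), which camera without the block did not (0.0605 for both).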

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

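The tests of immune cells, library depth and type I interferon genes, and the splits fitted with the replicate number as a block, were chosen after the result was seen.

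The dOVA line differed from its parent by another amount in MeVa2.1 than in MeVa2.2 for 6 named genes, by the test of that difference. On the log2 scale it was 3.55 for Sirpa, 3.49 for Rnf130, 3.11 for Rap1gap2, 2.16 for Trib1, -3.72 for Carmn and -2.49 for Pcdhgb2. The list tests of the same difference gave medians of -1.31 for MHC class I genes, -1.99 for interferon-stimulated genes and -0.70 for chemokines and cytokines. With an estimated correlation, adjusted p = 0.243, 0.563 and 0.563 in that order, so none of the 3 calls held. The edgeR test over all genes called 0 members of these lists. Lgals3bp differed by -4.37 (SE 0.83, adjusted p = 0.0840, so not called): every library of MeVa2.2.dOVA was higher than those of MeVa2.2, and every library of MeVa2.1.dOVA lower than those of MeVa2.1. For the count of 12 genes, 100 of the 200 different splits of the libraries within the 2 origins were drawn. Of these 7, the real one included, called as many, and the highest other called 2412. Chance is not excluded for that count. Of the 6 others, 5 parted MeVa2.2 replicates 1 and 3 and MeVa2.2.dOVA replicate 3 from the other libraries of the MeVa2.2 lines, which points to a structure of the samples other than the lines. With the replicate number as a block the count was 118, and 3 of the same 100 splits called as many, the highest other 1709. Of the 19 drawn splits that part all 6 same-numbered pairs, as the real one does, the real one alone called as many and the highest other called 23. These 19 are too few for a share under 0.05, and a split that calls 1709 points to a structure of the samples. The numbers were also not treated as pairs in the MeVa2.2 lines, since the correlation for replicate 1 (0.082) lay under the limit of 0.1.

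In the comparison of the dOVA lines the interferon-stimulated genes were lower as a list in MeVa2.1.dOVA (adjusted p = 9.22e-21, and adjusted p = 0.483 with an estimated correlation). Immune cells in the MeVa2.2.dOVA libraries are argued against, since their summed immune marker level was 0.719 times that of MeVa2.1.dOVA. Library depth is argued against too, with a log2 ratio of mean total counts of -0.055. Only the 13 genes named as type I interferons between Mrpl48-ps and Gm12669 on chromosome 4 were counted, and none outside that interval. Absence of these 13 genes in the MeVa2.1 lines stays open as a hypothesis. They had 16 counts in the 6 libraries of the MeVa2.2 lines and 0 in those of the MeVa2.1 lines. Of the 16, Ifnz held 11 and Ifne 5, and replicate 1 of MeVa2.2 had 0, too few to decide. A difference between the lines that does not run through the 13 genes was not tested and may equally account for it.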

How the results depend on the processing

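Leaving out all libraries of one number was chosen after the results were seen; the other alternatives were not. DESeq2 size factors, upper-quartile factors and the filter of 1 CPM left each count of changed genes within 1.5 times its value. In the order MeVa2.1.dOVA against MeVa2.1, MeVa2.2.dOVA against MeVa2.2, parents, dOVA lines and difference of differences, the counts were 68, 278, 627, 1574 and 12. The DESeq2 Wald test called 389, 950, 1216, 2380 and 272. With no filter, 272, 729 and 969 were called in the first 3 and 161 in the last. A fit to the compared lines alone called 25, 5, 397 and 1025, and it called 45 of the 75 named genes of the pairwise comparisons. Blocking on the replicate number gave counts of 364, 1084, 1330, 3079 and 118; the overlap of the dOVA comparisons was 108 genes and that of the comparisons between origins 856. The block gave 36 list calls against 28. It lost the Schwann list in MeVa2.1.dOVA against MeVa2.1 and, besides the lists given between origins, gained proliferation (adjusted p = 0.0091), NF-kB genes (0.0404) and melanocyte differentiation (0.0402) in MeVa2.2.dOVA against MeVa2.2 and proliferation in the difference of differences (0.0184). No call of a named gene was lost with it. The numbers do not pair MeVa2.2.dOVA with MeVa2.2 by the check (correlations 0.082, 0.64 and 0.521), although by deviations from the line means all 12 libraries correlated best, among libraries of other lines, with one of their own number. With an estimated correlation 0 of the 28 list calls held. By fry 9 of the 28 held, and it called 14 in all. Without the libraries numbered 1, 2 or 3, edgeR called 0, 0 and 0 genes in MeVa2.1.dOVA against MeVa2.1 (643, 861 and 1727 at an unadjusted p under 0.05; 148, 198 and 386 by DESeq2), 3, 35 and 11 in MeVa2.2.dOVA against MeVa2.2, and 58, 211 and 375 between parents. Between dOVA lines it called 232 and 809 without those numbered 1 or 2, and for the difference of differences 0, 0 and 0 (510, 1064 and 1258 unadjusted; 104, 187 and 236 by DESeq2), and 31, 45 and 40 of the 81 named genes were called. With each library left out in turn, the counts ranged from 1 to 83, 20 to 447, 279 to 775, 796 to 2578 and 0 to 13, the lowest without MeVa2.1 replicate 1 (among others), MeVa2.2.dOVA replicate 2, MeVa2.1 replicate 2, MeVa2.2.dOVA replicate 2 and MeVa2.1.dOVA replicate 3, and named genes called from 47 to 71 and list calls from 22 to 39. The cholesterol list turned its direction in MeVa2.2.dOVA against MeVa2.2 without MeVa2.2 replicate 3 (adjusted p = 0.473), while its lowest adjusted p was 0.00213, without MeVa2.2 replicate 2. No named gene changed direction in any alternative. The 75 of the pairwise comparisons were chosen for libraries that do not overlap. Leaving out libraries could therefore hardly turn their direction, and the kept direction is no support for them. Of the values for named genes, 1317 kept the call and 459 lost it, and of the list tests 401 kept it, 102 lost it and 1 turned.

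The number of genes called was compared with other splits of the same 6 libraries, of which there are 10, too few for a share under 0.05. For MeVa2.1.dOVA against MeVa2.1, 1 of 10 splits called as many, with 68 for the real split and 0 for the highest other. The parents gave 1 of 10 (627 and 0) and the dOVA lines 1 of 10 (1574 and 0). In these 3 comparisons the other splits that part all 3 same-numbered pairs had at most 723 genes at an unadjusted p under 0.05 and those that part 1 pair at most 3795, all with 0 called by edgeR, the only tool run on splits. MeVa2.2.dOVA against MeVa2.2 gave 2 of 10, with 278 for the real split. A split of MeVa2.2 replicates 1 and 3 with MeVa2.2.dOVA replicate 3 against the other 3 called 2614, which points to a structure of the samples. Mean log2 CPM over the proliferation list, looked at after that split was seen, differed along it. It was 6.41 and 7.08 in MeVa2.2 replicates 1 and 3 and 6.68 in MeVa2.2.dOVA replicate 3. In MeVa2.2 replicate 2 it was 4.96, and in MeVa2.2.dOVA replicates 1 and 2 it was 5.195 and 5.216. A low replicate 2 was not particular to the MeVa2.2 lines. The proliferation mean was 6.12, 5.55 and 6.83 in replicates 1, 2 and 3 of MeVa2.1 and 6.545, 5.27 and 6.59 in those of MeVa2.1.dOVA. The mean over p53 targets, given below, was highest in replicate 2 in 4 of 4 lines, and a link between the 2 lists was not tested. How far the list differences between MeVa2.2.dOVA and MeVa2.2 follow the split was not tested.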

Other observations

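All tests in this part were chosen after the result was seen.

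Among p53 target genes, a list of 23 chosen after their values were seen, Mdm2, the ubiquitin ligase of p53, was at 1620 CPM in MeVa2.1.dOVA replicate 2 and 1612 in MeVa2.2.dOVA replicate 2, against 465 and 478 in replicate 2 of MeVa2.1 and MeVa2.2. In replicates 1 and 3 Mdm2 was at 313 and 370 CPM in MeVa2.1.dOVA against 243 and 249 in MeVa2.1, and at 1162 and 273 in MeVa2.2.dOVA against 273 and 181 in MeVa2.2. Of 22 tested targets edgeR called 0 in either dOVA comparison, with 2 at an unadjusted p under 0.05 in MeVa2.1.dOVA against MeVa2.1 and 8 in MeVa2.2.dOVA against MeVa2.2. In the same order DESeq2 called 0 and 5. Cdkn1a, a cell-cycle inhibitor, was at 1290 and 964 CPM in replicate 2 of MeVa2.1.dOVA and MeVa2.2.dOVA, against 603 and 411 in replicate 2 of their parents. Not all targets went that way. Gdf15 was at 4.95, 6.39 and 2.52 CPM in replicates 1, 2 and 3 of MeVa2.1.dOVA, against 20.9, 19.6 and 4.64 in MeVa2.1. In MeVa2.2.dOVA it was at 1.90, 1.44 and 0.39, against 7.96, 16.6 and 2.32 in MeVa2.2. Pmaip1 was at 13.7, 7.59 and 4.90 CPM in MeVa2.2.dOVA, against 55.6, 32.8 and 15.6 in MeVa2.2. In MeVa2.1.dOVA Pmaip1 was higher than in MeVa2.1 in each same-numbered pair. Of the MHC class II genes, also chosen after their values were seen, H2-Aa was at 0.873, 0.612, 0.987 and 0.791 CPM in replicate 1 of MeVa2.1, MeVa2.1.dOVA, MeVa2.2 and MeVa2.2.dOVA and at 0 in all other libraries, and H2-Ab1 at 0.655, 1.04, 0.755 and 0.949 and at 0 elsewhere. Cd74, the invariant chain, was at 2.95, 2.75, 2.03 and 5.01 CPM in these libraries, at 4.65 in MeVa2.2.dOVA replicate 2 and at most 0.39 in the others, while H2-DMa was at 1.33 to 3.62 CPM over all libraries, highest in MeVa2.2 replicate 2.

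The mean log2 CPM of 22 tested p53 targets was highest in replicate 2 in 4 of 4 lines, at 5.87, 6.77, 6.17 and 6.77 in MeVa2.1, MeVa2.1.dOVA, MeVa2.2 and MeVa2.2.dOVA. It was higher in the dOVA line in 6 of 6 same-numbered pairs, by 0.50 on average (range 0.03 to 0.90). Because the list was chosen from these values, neither count tests a state shared by same-numbered libraries or presence of dOVA, and both stay open, as do culture and handling, since the labels do not say what the numbers stand for. Library depth is argued against for replicate 2 against replicate 1, whose total counts differed by at most 1.124 times. It stays open for replicate 3, which had the lowest mean in 3 of 4 lines and 1.385 to 1.995 times the counts of the deeper of the other replicates.

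On chromosome 4 the tested genes from Klhl9 to Dmrta1, some of them chosen after their values were seen, were nearly silent in both MeVa2.1 lines. Unrelated silencing of single genes is argued against: the longest run of adjacent tested genes with a mean of at least 1 CPM in the MeVa2.2 lines and under 1% of it in the MeVa2.1 lines was 4, and the longest in 10000 shuffled orders was 3. All 9 tested genes of the stretch were under 1%, and those under 1 CPM in the MeVa2.2 lines, such as Cdkn2a, break the run. Of the flanking genes that bound the interval, Mrpl48-ps, a pseudogene by its symbol, had 134 counts in the MeVa2.1 lines against 100 in the MeVa2.2 lines. Gm12669 had 1937 against 2173. The next tested gene beyond Mrpl48-ps, Hacd4, was at 46.1% of the MeVa2.2 level (359 counts against 771). Loss of one chromosome segment stays open as a hypothesis, and silencing of the whole segment would give the same values: the 66 untested genes between the flanking genes, which lie 3.21 Mb apart, had a pooled level of 6.91% of the MeVa2.2 lines (12 counts against 134), between the 1% and 10% set as bounds. Of the 12 counts 11 lay beyond Dmrta1, 7 of them in Gm12634 (against 9), and up to Dmrta1 there was 1 against 93; the interval was widened to the flanking genes after a narrower one was found to hold no counts, and DNA data, not used here, would be needed to decide.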
